A study of Homo sapiens with 8 samples.

How the data were processed

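In situ Hi-C with the enzyme MboI was performed by the authors on HEK293FT lines with the NUP98-HOXA9 fusion, with an intact or a phenylalanine-to-serine disordered region, per the labels' protocols. There were 8 libraries, 4 per line. Per the submitters' processing notes, BWA 0.7.17 and Juicer 1.11.09 were used with build hg19. Loops were called with juicer_tools 1.11.09, per the file headers, at 10 kb. The labels name a merged map for each line, and there is 1 loop list per line. How the merged maps were filtered is not given in the sources used here. The contact maps, and the total depth per library, were not analysed here. Columns of other samples numbered 0.

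The deposited lists give for each loop an observed contact count at its pixel, not normalized, per the file headers. They give 4 expected values from the neighbourhood of the pixel (donut, bottom-left, horizontal and vertical), on the scale of that count, per the file headers. The authors' deposited table gives a q-value against each of the 4 neighbourhoods, all below 0.1, and the number of pixels merged into the loop. Enrichment below is observed over donut-expected contacts.

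Anchors were compared with the reference build GRCh37 and all lay inside its chromosomes. Gene positions came from GENCODE release 44 lifted to GRCh37. A table of GRCh38 genes served for older gene symbols alone, and no coordinates were taken from it. Coordinates are the 1-based start of each 10 kb anchor.

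Loops of the lists were matched one to one by least total distance, with both anchors within 20 kb. Chance matching came from shifting 1 list by 0.5, 1 and 2 Mb in each direction. Relative depth was the median ratio of donut-expected counts at identical pixels. Strength was compared as the log2 ratio of enrichment, with a counting interval from both observed counts and a 1.5-fold size rule. Medians have bootstrap intervals of 1000 draws and shares have exact Clopper-Pearson 95% intervals. Both cover counting error only, since no replicates could be separated in the merged lists. Loop length, anchor sharing, chromosomes, motifs and gene lists were placed among 10000 random draws of as many loops from the same list. Such a percentile describes these 2 merged maps, not the conditions. The draws and the intervals of shares treat loops as independent. In the WT list, 64.2% of loops had an anchor within 20 kb of an anchor of another loop, so percentiles of gene lists can be too extreme.

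For the comparison at equal depth, WT observed counts were thinned at random 100 times to the FS depth and their expected counts scaled. Loops were kept where they reached the lowest observed count, or its 5th percentile, in the FS list at a like expected count in each of the 4 neighbourhoods. This rule stands in for the caller, which was not rerun.

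CTCF motifs were scanned in both strands of the reference with a rounded core matrix written down from general knowledge of the motif, not taken from a database, at a match p of 1e-05 (12.7 bits). A gene was placed at a loop where its start site lay within 10 kb of an anchor. The 16 gene lists, the tests and the alternative settings not listed as later additions were set before the data were examined. The list of zinc finger genes holds every protein-coding gene whose symbol begins with ZNF. A single loop can touch several genes of a cluster.

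The text names the 12 WT-only and 8 FS-only loops of highest enrichment among those with at least 30 contacts, and the 5 shared loops with the largest difference in each direction. It names all genes of the HOX, TALE and leukaemia lists with a list-specific loop, and up to 4 genes of every other list. A few of these loops and genes are not reported here. Loops are named by the protein-coding start sites within 10 kb or the genes the anchors overlap. Length classes, windows of 1 Mb, thinning per loop, depth per chromosome, weighting of shared loops and the background at single loci were added after the data were seen.

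Matching, the size rule, the percentiles and the motif scan were tested on simulated data. Of 2417 planted shared loops 99.8% were matched, and of 2371 unrelated ones 0.506%. The size rule counted 97% of 200 loops with a 2-fold change and 47.5% of 200 with a 1.5-fold change. Alternatives were other tolerances, stricter loop thresholds, other backgrounds, other motif thresholds and anchor widths, and other start site windows. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.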

Results

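In situ Hi-C, which joins DNA ends that lie close together in the nucleus and counts the joined pairs, was performed on 2 stable lines of HEK293FT, a human embryonic kidney cell line. One line carried NUP98-HOXA9, a leukaemia fusion of the intrinsically disordered part of the nuclear pore protein NUP98 with the DNA-binding part of the homeobox factor HOXA9. The other carried the same fusion with phenylalanines of the disordered region replaced by serines. The comparison asked how chromatin loops differ between cells with the intact and the mutated disordered region. Each line had 4 libraries, from 2 biological replicates with 2 libraries each, and the authors called loops once per line on a merged map. The values below come from these merged lists and therefore carry no replicate error. No test between conditions was possible from the lists, and every interval covers counting error only. The loop lists are called the WT list and the FS list. A loop found in one list alone is WT-only or FS-only, which means that it was not called in the other list. The contact count of the other map at that position was not used here.

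The WT list held 4788 loops and the FS list 2826, a ratio of 1.69 (95% interval 1.62 to 1.78). Both anchors lay within 20 kb in both lists for 1983 loops, against a mean of 32.5 when 1 list was shifted along the chromosomes. The other 2805 loops of the WT list were WT-only, 58.6% of it (exact 95% interval 57.2 to 60.0). The FS list held 843 FS-only loops, 29.8% of it (28.1 to 31.6). The median observed contact count per loop was 68 in the WT list and 65 in the FS list, and the median ratio of observed to donut-expected contacts was 2.67 in both. List-specific loops were weaker calls than shared loops. A single pixel made up 70.3% of WT-only loops and 83.9% of FS-only loops, against 24.8% of shared loops in the WT map and 40.9% in the FS map. The expected counts at 999 identical pixels put the FS map at 0.866 of the depth of the WT map (0.859 to 0.871). The WT list thinned to that depth kept on average 3649 loops, 1.29 times the FS list, by the lowest counts the FS list shows. By the 5th percentile of those counts it kept 3419, which was 1.35 times the 2535 FS loops that pass the same limit and 1.21 times the whole FS list.

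**Figure D1:**
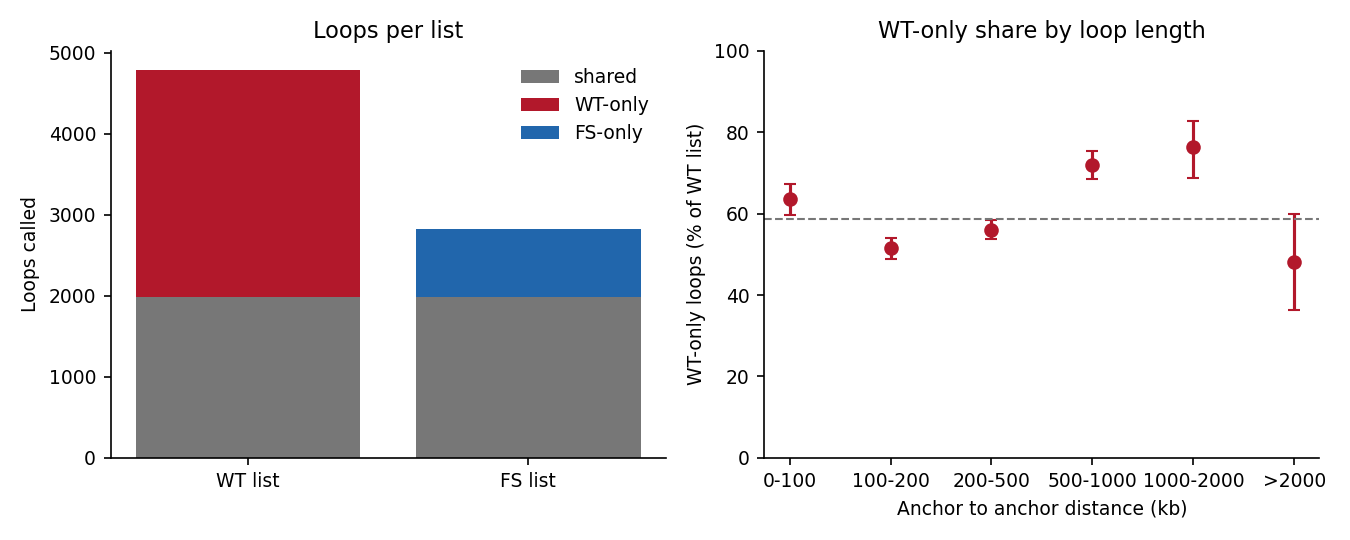
Left, number of loops called in each list, divided into shared and list-specific loops; right, WT-only loops as a percentage of the WT list (points, with exact 95% intervals) by anchor to anchor distance in kb, with the whole-list share of 58.6% as a dashed line. The share was 63.6% below 100 kb (59.8 to 67.3), 72% at 500 to 1000 kb, 76.3% at 1000 to 2000 kb and 48% beyond, the lowest of the classes.

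The loops that both lists held differed little in strength between the maps. They had to be called in both maps, which leaves out loops much weaker in one of them. The median log2 difference in observed over expected contacts was 0.04 (WT minus FS, bootstrap 95% interval 0.03 to 0.05) over 1983 loops. Its standard deviation of 0.26 across loops was close to the 0.25 that counting error gives. By the rule of a 1.5-fold difference with a counting interval that left out 0, 33 loops were stronger in the WT map and 13 in the FS map. These were 46 of 1983 loops. Of 4388 loops simulated with no change, 2.69% met the same rule. The simulation drew on the counts of the whole WT list (median 68). Shared loops had higher counts (medians of 84 in WT and 69 in FS), so 2.69% is not a matched rate for them. The 5 largest differences toward WT came mainly from the expected counts, and 4 of them belonged to pairs megabases apart. The largest, on chromosome 12 from 9550001 to 31270001, differed by 2.19 with 15 contacts in WT and 14 in FS. The others were a pair ending in TMEM132B at 125800001 (1.35, 18 and 19 contacts), one on chromosome 5 from 21530001 to 29420001 (1.22, 43 and 38) and one touching NXPE1 and NTM (1.19, 17 and 12). The fifth, a loop at ADAMTS1, a secreted metalloprotease gene (chromosome 21, 28220001 to 29070001), differed by 1.13 (0.64 to 1.63), with 75 contacts against 11.9 expected in WT and 56 against 19.6 in FS at a pixel 10 kb away. Toward FS, an intergenic loop on chromosome 5 from 101070001 to 101350001 differed by -1.44, with 32 contacts in WT and 29 in FS. A loop from ANTXRL to ZNF488 (chromosome 10, 47640001 to 48350001) differed by -1.0 (-1.48 to -0.53), with 55 and 103 contacts. A loop inside the receptor gene ERBB4 (chromosome 2, 212770001 to 212960001) differed by -1.09 although WT had more contacts, 29 against 9.06 expected, with 18 against 2.65 in FS at a pixel 10 kb away. One ending in GRK3 differed by -1.23 (22 and 41 contacts). A pair touching ODF3L1 (-1.26) spanned 2140 kb, with 14 and 12 contacts. Of these 5, those at ZNF488 and GRK3 alone had more contacts in the FS map.

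WT-only loops had a longer median distance than the rest of their list, although their share was also raised below 100 kb. The median was 250 kb against 210 kb for shared loops, above 10000 random draws of as many loops from the WT list (percentile 100). FS-only loops were shorter, with a median of 190 kb against 220 kb (percentile 1.28), an order that was lost when weaker loops were left out. By length class, examined after the lists were seen, the WT list held 1.55 times as many loops as the FS list below 100 kb, 1.51 times at 100 to 200 kb and 1.66 times at 200 to 500 kb. The ratio was 2.46 at 500 to 1000 kb and 2.81 at 1000 to 2000 kb, but 1.53 beyond 2000 kb, with 75 and 49 loops. The draws were not matched on contact count, whose median in the WT map was 58 for WT-only and 84 for shared loops. Thinning was not applied by length class, so whether depth alone could give these length differences was not tested. WT-only loops also shared anchors with one another. Of these loops, 51.3% had an anchor within 20 kb of an anchor of another WT-only loop, against 48.9% in random draws (95% of draws 47.1 to 50.7, percentile 99.8). For FS-only loops the share was 14.9% against 16.5% in draws (percentile 17.4).

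At the HOX clusters, which encode the homeobox factors that pattern the body axis and are targets of NUP98-HOXA9 in leukaemia, the WT list held 22 loops and the FS list 12. Of the 22, 11 were WT-only (50%, exact 95% interval 28.2 to 71.8), which was within the central 95% of random draws (percentile 21.1), and 1 FS-list loop was FS-only. The HOXA cluster (chromosome 7, 27132612 to 27239710) had 10 loops in the WT list and 8 in the FS list, 8 of them shared. The HOXB cluster (chromosome 17, 46605888 to 46806112) had 4 and 1, HOXC (chromosome 12, 54332615 to 54449814) 3 and 1, and HOXD (chromosome 2, 176957449 to 177055635) 5 and 2. The HOXB loop with the highest enrichment joined an anchor at 46330001 to the anchor at 46690001, which carries HOXB3, HOXB6, HOXB8 and HOXB9. It had 171 contacts against 37.5 expected, 4.56-fold. A second joined 46410001 to HOXB4 and HOXB5 at 46660001, with 228 contacts against 69.4 expected. The FS list instead called a loop from 46410001 to 46690001, with 85 contacts against 32.5 expected. HOXB2 and HOXB13 had 1 short WT-only loop each, of 1.84-fold and 1.91-fold.

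The anchor of HOXD3, HOXD4 and HOXD8 at 177000001 looped to 177140001 in the WT list alone, with 134 contacts and a 4.26-fold enrichment, and shared a loop to 177500001 with the FS list. HOXD13 had a weaker WT-only loop of 30 contacts. HOXC4 and HOXC5 had a WT-only loop of 182 contacts to 54590001 (3.35-fold), and HOXC10 and HOXC11 one of 2.06-fold. At HOXA, the anchor of HOXA9, HOXA10, HOXA11 and HOXA13 at 27220001 looped to 28050001 (62 contacts, 3.14-fold), and that of HOXA3, HOXA5, HOXA6 and HOXA7 to 26690001 (60 contacts, 4.25-fold). A stricter rule, chosen after the data were seen, required a loop to pass the lowest FS counts in at least 95 of 100 thinnings to the FS depth. The rule used the genome-wide depth ratio of 0.866 everywhere. Of the WT-only loops, 1064 of 2805 (37.9%) met it. Of the shared loops, which the FS map did call, 1507 of 1983 (76.0%) met it. At HOX genes 9 of the 22 WT-list loops were WT-only loops that met it, against 4.89 in random draws. Their percentile of 97.4, the highest of the 16 gene lists, lay just inside the central 95%. This count joins being WT-only with passing the thinnings, and most shared HOX loops passed them too. The WT-only share of HOX loops, 50%, was below the 58.6% of the whole list. The other lists ranged from imprinted genes (0 of 10, percentile 4.31) to developmental transcription factors (16 of 49, percentile 95.7), with leukaemia genes at 4 of 23 (percentile 30.7).

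Of the TALE homeobox genes, which encode DNA-binding partners of HOX proteins, PBX3 and MEIS1 had loops. PBX3 (chromosome 9, 128509624 to 128729656) had 3 loops in the WT list and 0 in the FS list, with the strongest from 127520001 to 128510001 (37 contacts, 5.57-fold). Of the 3, 2 met the stricter rule, which was applied at the genome-wide depth and not at that of the region. The local FS background at 4 shared loops of the region was 0.698 of WT, lower than the genome's 0.866 but close to the 0.727 of the whole of chromosome 9. MEIS1 (chromosome 2, 66660584 to 66801001) had 2 and 1, the WT-only one to 66920001 with 45 contacts. The list as a whole had 4 WT-only loops of 5 (percentile 80.6).

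Genes associated with leukaemia had 23 loops in the WT list and 9 in the FS list, with 16 of the 23 WT-only (69.6%, 47.1 to 86.8, percentile 85.4). SOX4, a transcription factor gene on chromosome 6 (21593982 to 21598850), had 5 loops in the WT list and 0 in the FS list, led by a pair from 20860001 of 3.91-fold. Of the 5, 1 met the stricter rule, with 99, 88, 82, 1 and 0 of 100 thinnings passed. The FS background at the 1 shared loop near it was 0.588 of WT, below the genome-wide 0.866 used for the thinnings. EYA4 had 2 WT-only loops and no others, of 117 and 224 contacts. IGF2BP1 (chromosome 17, 47074747 to 47133507), an RNA-binding protein gene, was joined to the same 2 anchors as the HOXB genes, at 46330001 with 40 contacts (4.14-fold) and at 46410001 with 37 (3.44-fold). These passed the FS limits in 98 and 49 of 100 thinnings, so the second failed the stricter rule. IGF2BP1 also had 1 short FS-only loop. BCL6 had 2 WT-only loops of 23 and 29 contacts beside a shared one, and MYC 1 of 27 contacts that passed the FS limits in 11 of 100 thinnings. MECOM, HLX, IGF1R and RUNX2 had 1 WT-only loop each, which passed the FS limits in 87, 0, 91 and 13 of 100 thinnings. None of them met the stricter rule, nor did the WT-only loops of BCL6 (65 and 39). IGF1R also had 3 shared loops and HLX 1. CDK6 had 1 loop, FS-only, of 58 contacts and 2.65-fold.

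**Figure D2:**
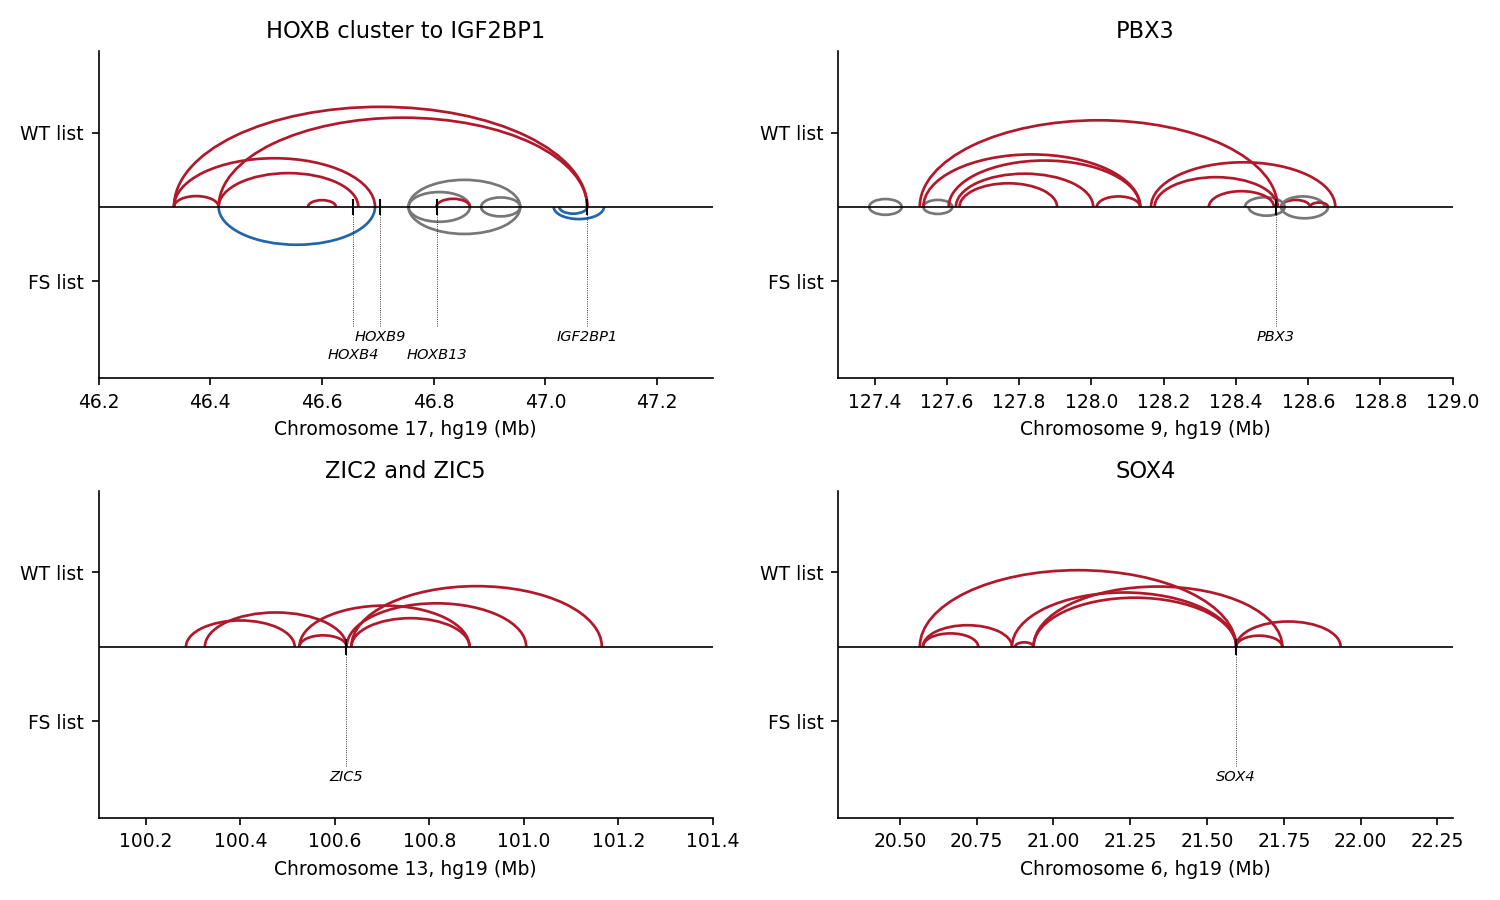
Loops called at 4 loci, chosen after the values were seen, as arcs between anchors (WT list above the line, FS list below; grey shared, red WT-only, blue FS-only) along hg19 coordinates in Mb. Arc height shows distance, not strength; at SOX4 and at ZIC2 and ZIC5 no FS-list loop was called in the plotted span.

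Genes of developmental signalling pathways had the highest percentile among 16 gene lists fixed before the data were examined, though lists with 5 or 6 loops reached larger shares (80% to 83.3%). Of their 36 WT-list loops, 27 were WT-only (75%, 57.8 to 87.9), at percentile 97.8 of random draws. The draws treat loops as independent, though several of the 27 lay at the same gene, such as 4 at BMPR2. The FS list had 13 loops, of which 7 were FS-only (53.8%, percentile 95.8), within the central 95% of draws. About 0.8 of 16 lists would lie outside the central 95% by chance, and the excess was lost with draws matched on loop length (percentile 94.1) and with start sites inside the anchor bin (percentile 78.5). BMPR2, a receptor for bone morphogenetic proteins, had 4 loops in the WT list and 0 in the FS list, the strongest of 4.71-fold on 22 contacts. The Wnt receptor gene FZD8 had 2 and 0, TGFB2 3 and 2 with none shared, and EPHB1 1 and 0. Other developmental transcription factors had 49 and 26 loops, with 30 of 49 WT-only (61.2%, percentile 63.8). ZIC2 and ZIC5, neighbouring zinc finger genes (chromosome 13, 100615218 to 100639019), had 5 WT-only loops and no FS-list loop. The strongest ran from 100520001 to 100620001 with 115 contacts against 22.2 expected (5.17-fold), and 4 of the 5 met the stricter rule. The local background could not be compared, since the region held no shared loop of equal length. Chromosome 13 as a whole had the highest ratio of WT to FS loops, 2.29. FOXP1 had 2 WT-only loops, led by 94 contacts from 71100001 to 71630001 on chromosome 3, and DLX5 1 of 3.59-fold. Kidney development genes had 5 loops in each list. EMX2 had 1 WT-only and 1 FS-only loop, OSR1 had 1 WT-only loop, and GDNF 1 FS-only loop.

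The other lists lay within the central 95% of draws for both classes. Neuronal genes had 6 WT-list and 8 FS-list loops, with 2 WT-only loops at CNTN1, 2 FS-only loops at the guidance gene SLIT3 and 1 of each class at ELAVL3. Genes of loop architecture factors had 5 and 3, with 1 WT-only loop each at PDS5A, NIPBL and STAG1 and 1 FS-only at SMC3. Nuclear pore genes had 6 and 2, with WT-only loops at NUP133, NUP50, TPR and SEH1L. Housekeeping genes had 11 and 5, with WT-only loops at RPL7, YWHAZ, TFRC and EEF1A1. Blood lineage markers had 5 and 1, with WT-only loops at LYZ, CD14, ELANE and EPOR. These passed the FS limits in 94, 93, 0 and 23 of 100 thinnings, so none met the stricter rule. Imprinted genes had 10 and 6, with 4 of 10 WT-only (40%), 2 of them at IGF2 and 1 each at MAGEL2 and CDKN1C. Clustered protocadherin genes had 2 and 1, where 1 WT-only loop touched PCDHA10, PCDHA11, PCDHA12 and PCDHB1. Histone genes had 6 and 1, where 1 WT-only loop touched H2AC7, H2AC11, H2AC12 and H2BC11 and passed the FS limits in 37 of 100 thinnings. H2AC12 had 2 WT-only loops in all. Olfactory receptor genes had 13 and 5, with WT-only loops at OR4A16, OR5I1 and OR5BS1P and an FS-only loop at OR52M1. Genes named ZNF had 56 and 30, with 4 WT-only loops at ZNF608, 1 at ZNF534, and FS-only loops at ZNF99 and ZNF804B. Over all protein-coding genes, 1640 had a start site at loops of the WT list alone, 658 at loops of the FS list alone, and 1508 at both.

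**Figure D3:**
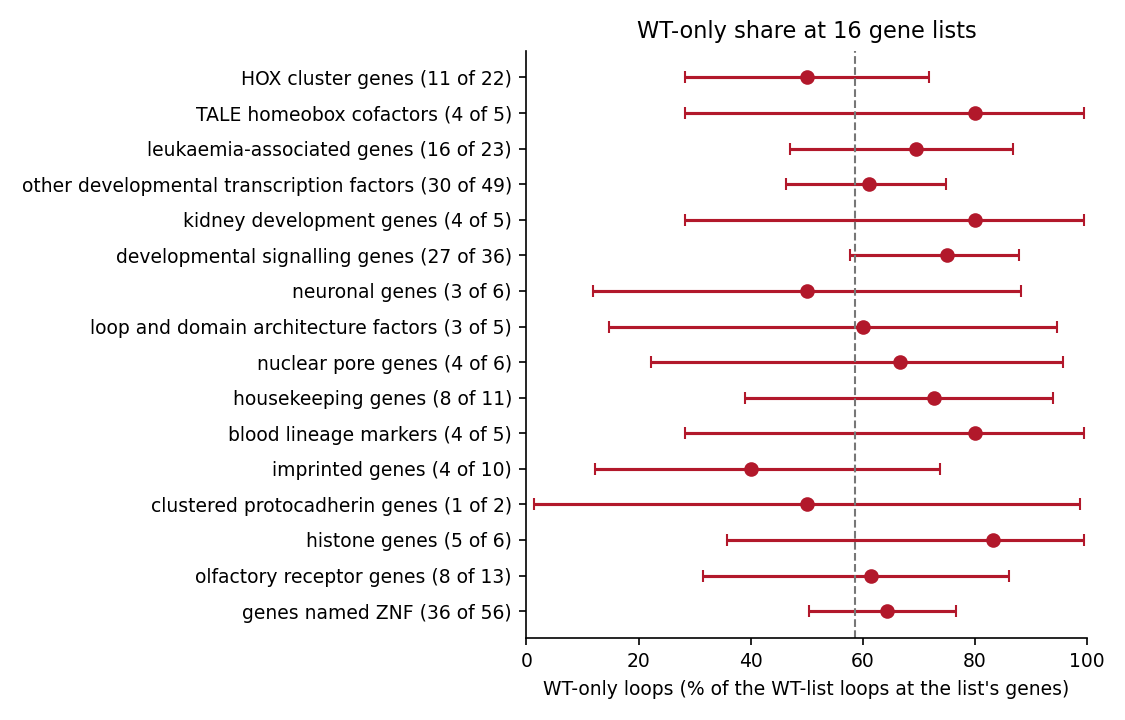
WT-only loops as a percentage of the WT-list loops with a start site of each list's genes within 10 kb of an anchor (points, with exact 95% intervals), with the counts in brackets. The dashed line marks the whole-list share of 58.6%; the interval of each of the 16 lists included it.

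By observed over expected contacts, the strongest WT-only loop with at least 30 contacts ran on chromosome 1 from ENAH at 225690001 to an intergenic anchor at 229300001, with 78 contacts against 2.97 expected. Next was a pair of DDAH1 with PDZK1 and CD160 over 59740 kb (11.7-fold), which passed the FS limits in 2 of 100 thinnings. The anchor in CDKN2C at 51440001 looped to OSBPL9 (9.57-fold) and EPS15 (7.98-fold), and FNBP1L looped to ARHGAP29 (9.44-fold). On chromosome 14 an anchor in TMEM260 looped to NAA30 and to KTN1, and an intergenic pair at 28120001 and 28840001 reached 7.47-fold. A pair of STX12 with TCEANC2 over 26440 kb (7.15-fold) passed the FS limits in 62 of 100 thinnings. The expected counts of the DDAH1 and STX12 pairs, 3.42 and 5.45, were far above the median of 0.111 for WT-list pairs over 10 Mb. Contacts were thus raised around these pixels as well, and whether these 2 pairs are chromatin loops was not tested. LIN28B, an RNA-binding protein gene, looped to ATG5 (43 contacts, 7.08-fold), NEO1 to NPTN (84 contacts, 6.92-fold), and an intergenic anchor at 66610001 on chromosome 2 to C1D (6.49-fold). The strongest FS-only loops were an intergenic pair on chromosome 1 at 192900001 and 193370001 (11.1-fold) and a loop inside MAGI2 (9.27-fold). Others lay inside PLCB4 (7.79-fold), between PLCB1 and PLCB4 (6.36-fold) and inside RUNX1 (5.39-fold). One reached the start sites of COX11 and STXBP4 (65 contacts, 7.02-fold), and an intergenic pair on chromosome 4 at 181350001 had 6.29-fold.

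Anchors of list-specific loops carried fewer matches to the motif of CTCF, the insulator protein at which loops commonly end. A match lay at both anchors of 51.4% of WT-only loops (49.5 to 53.2), 50.2% of FS-only loops (46.7 to 53.6) and 69.3% of shared loops (67.2 to 71.3). Regions shifted by 100 kb gave 22.0%, 23.1% and 24.8%. Neither anchor had a match in 16% of WT-only loops (14.7 to 17.5), 11.4% of FS-only loops (9.32 to 13.7) and 5.70% of shared loops (4.72 to 6.81). Among loops with motifs of 1 orientation at each anchor, 65.0% of WT-only pairs pointed toward each other (61.1 to 68.7), 71.9% of FS-only pairs (65.1 to 78.0) and 78.3% of shared pairs (74.6 to 81.7). The mean GC content of the anchors was 43.0% in WT-only, 43.7% in FS-only and 45.1% in shared loops.

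**Figure D4:**
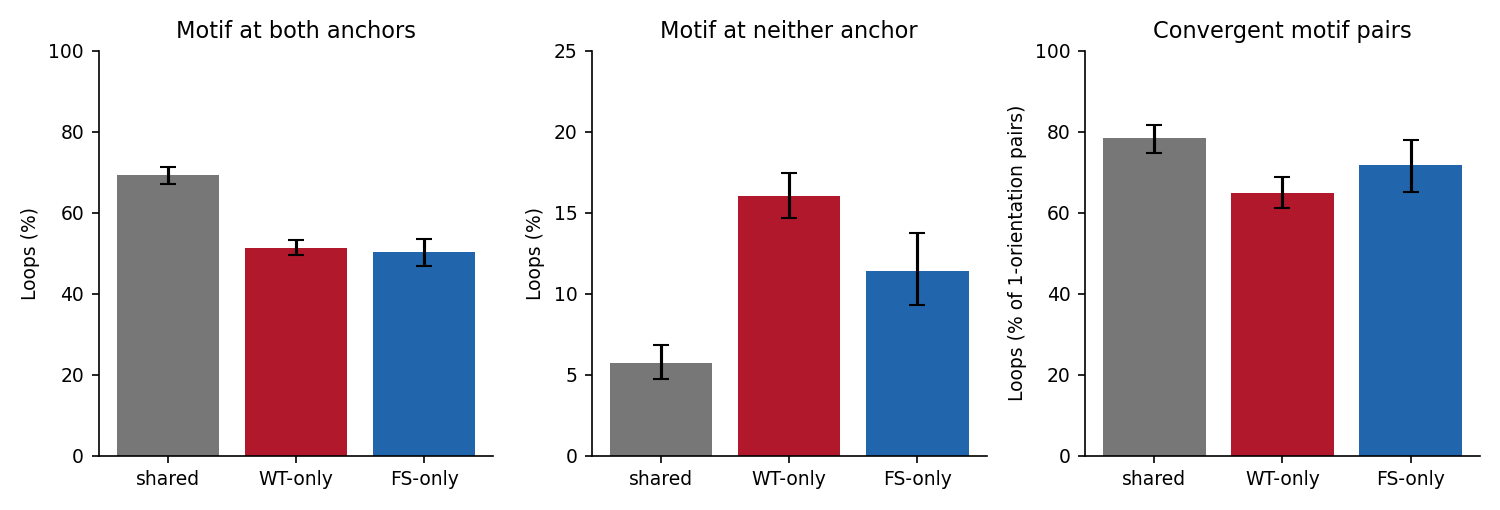
Percentage of shared (1983, anchors of the WT list), WT-only (2805) and FS-only (843) loops with a CTCF motif match at both anchors, at neither anchor, and in convergent orientation among loops with 1 motif orientation per anchor. Bars give the share and whiskers the exact 95% interval; the axis of the middle panel ends at 25%.

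The WT list held more loops on each of the 23 chromosomes, with ratios from 1.26 on chromosome 11 to 2.29 on chromosome 13, and the interval lay above 1 on 21 of them. The share of WT-only loops was above the central 95% of draws on chromosome 13 (71.8%) and below it on chromosomes 22 (45.1%), 11 (49.4%) and, narrowly, 17 (51.9%, percentile 2.31). The background ratio between the maps also differed by chromosome. The FS over WT ratio at identical pixels was 0.727 on chromosome 9, 0.739 on chromosome 3 and 1.13 on chromosome 11, the 1 chromosome where the FS map was deeper.

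**Figure D5:**
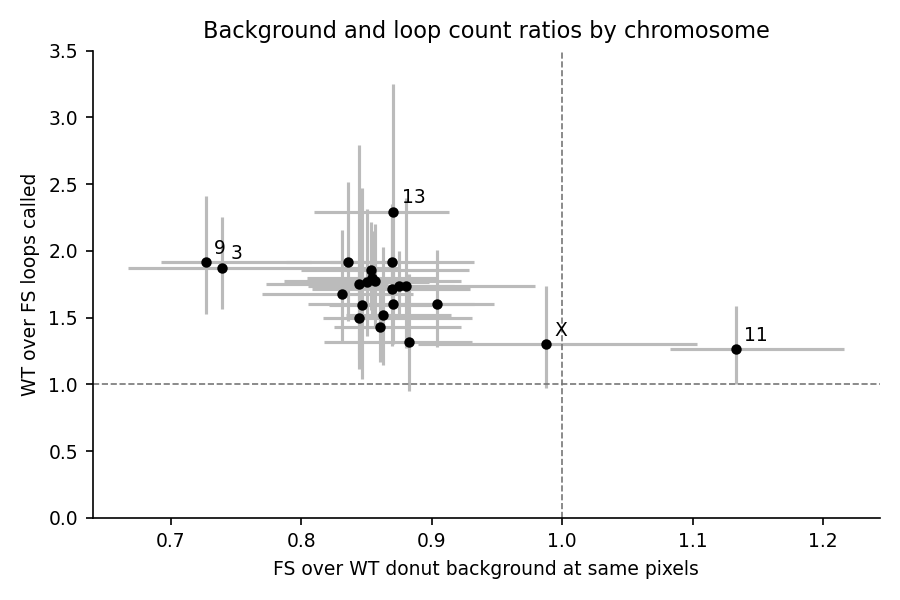
Ratio of loops called (WT over FS, with 95% counting interval) against the FS over WT donut background at identical pixels (median, with quartiles) for each of 23 chromosomes, 5 of them labelled. Dashed lines mark a ratio of 1; chromosome 11 lay at a background of 1.13 and a loop ratio of 1.26.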

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

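No paired analysis was possible because each line has 1 loop list from a merged map, and for the same reason no replicate was left out and no other splits of the samples were made. Of 248 values under other settings, 218 kept their direction and side of the threshold or stayed within 1.5 times or their interval. Gene lists gave 142 of the 248, with 138 unchanged, but a list with 1 loop could not leave the central 95% of draws. A further 23 left out 1 chromosome each, and the WT-only share stayed between 58.3% and 58.9%. All 24 values that moved and the 1 that was reversed lay among the rest, so the total says little about those. The cause of the changes below was not tested, except that stricter filters leave fewer loops. Thinning per loop, matching on length and depth per chromosome were chosen after seeing the data.

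With all 4 q-values at or below 0.01, the lists held 2868 and 1504 loops, a ratio of 1.91, with 1080 shared, 1788 WT-only and 424 FS-only loops, and 4.22 WT-only per FS-only loop. Requiring exactly the same pixel left 999 shared and 1827 FS-only loops, and 2.07 WT-only per FS-only loop, against 2.93 at 10 kb. Of the WT-only loops, 1064 passed the FS limits in 95 of 100 thinnings. The bottom-left background gave a depth ratio of 0.85 and a median log2 difference of 0.022. The number of loops stronger in WT was 50 with the vertical background, 9 at identical pixels and 6 by a 2-fold rule, and the number stronger in FS was 4 at identical pixels and 5 by the 2-fold rule. The median length of FS-only loops was 200 kb at identical pixels and no longer outside the draws, and 240 kb, turned to the longer side of them, at an enrichment of at least 2.

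The convergent share of WT-only pairs was 76.9% with a stricter motif threshold, 53.9% with a looser one and 54.6% with wider anchors. Shared pairs, at WT anchors, had 86.8%, 67.8% and 78.8% at these settings and stayed above the WT-only pairs at each. For FS-only pairs it was 55.2% with the looser threshold and 63.7% with wider anchors. The WT-only share of developmental signalling genes fell inside the draws with start sites inside the anchor bin (66.7%) and with draws matched on length (75%). That of leukaemia genes moved above them with start sites inside the bin (91.7%). The FS-only share of HOX genes was 0% at a tolerance of 50 kb, below the draws.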

Other observations

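The tests of the chromosomes, of depth with weaker enrichment and of chromosome 11 were chosen after the result was seen, as were the windows and the single loci. WT-only loops were also counted by 1 Mb windows, taking loops of up to 2 Mb by their midpoint. The window with the most was chromosome 7 from 26000001 to 27000000, beside the HOXA cluster, with 11 and 6 shared loops. Chromosome 10 from 22000001 to 23000000, which holds the Polycomb gene BMI1, had 10 and 1 shared loop. Next came chromosome 2 from 177000001 to 178000000 at HOXD with 9 and 1 shared loop. Windows with 8 included those of MEIS1, of ARID5B and of FOXC1, FOXF2 and FOXQ1, with 1 shared loop each. The window of the HOXB cluster had 8 and 3 shared loops. Another with 8 was chromosome 20 from 43000001 to 44000000, with 0 shared loops and many genes, among them ADA, SDC4 and STK4. The highest count was within the range of the highest window in random draws (mean 10.3, 95% of draws 8 to 14). Both lists held pairs over 10 Mb apart, 38 in WT and 27 in FS, of which 23 were shared and 15 had the same pixel, with median expected counts of 0.111 and 0.182.

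More loops were called in the WT list. A gain or loss of a few chromosomes was argued against, since the WT list held more on 23 of 23. Depth could account for part of the excess: thinning to the FS depth left 1.29 times as many loops as the FS list, between the bounds of 1.1 and 1.5 set beforehand, and adding the slightly weaker enrichment of the FS map left 1.18 times. By the 5th percentile limit the latter was 1.08 over the whole FS list, below the bound of 1.1, and 1.204 over the FS loops that pass the same limit, so the settings disagreed. On chromosome 11, chosen as the 1 chromosome of 23 where the FS background was deeper (1.13 times that of WT), the WT list still held 1.26 times as many loops (1.01 to 1.59), which argues against depth as the whole cause on that chromosome, though the lower bound is close to 1. Other values went with depth. Over the 23 chromosomes the loop ratio fell as the FS over WT background rose (Spearman -0.476). On chromosome X, with a background of 0.988, the ratio of 1.299 had an interval that included 1 (0.97 to 1.74). Chromosome 22 went the other way, with a like ratio of 1.319 (0.954 to 1.83) at a background of 0.882. How far depth and enrichment explain the rest cannot be told apart from an effect of the disordered region, which stays open without replicate maps. Other differences between the 2 lines are confounded with the mutation, and replicate maps of the same lines would not separate them.

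WT-only loops had a CTCF motif at neither anchor more often than shared loops, 16% against 5.70%. Closeness to the FS count limits was argued against. WT-only loops that passed these limits in 95 of 100 thinnings lacked the motif in 17.5% (15.2 to 19.9). Those that passed in under 50 lacked it in 16.2% (13.8 to 19.0). The thinnings start from the same counts that led to the call, so they cannot exclude calls raised by chance. Weighting shared loops to the anchor GC content of WT-only loops gave 8.71%, and to their length and contact count 9.27%. To all of these and enrichment together it gave 9.0% (7.02 to 11). As weighted, each closed part of the gap. The joint weighting used 3 coarse groups of each trait and left out merged pixels and q-values. The median highest q-value was 0.0141 in WT-only and 9.82e-05 in shared loops, so calls raised by chance stay open here too. FS-only loops lacked the motif in 11.4%, so the pattern may belong to list-specific loops of either line. A hypothesis left open is that part of the WT-only loops form without CTCF; binding of CTCF or of the fusion was not analysed here.

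Loops from 2 anchors on chromosome 17 to the HOXB genes and to IGF2BP1 were called in the WT list and not at those pixels in the FS list. A higher copy number or coverage in the WT map was argued against for the surrounding region as a whole. There, 6 shared loops had a median FS over WT background of 0.910 (lowest 0.829, highest 1.06). None of them lay at the HOXB genes or IGF2BP1, so a background difference at the cluster itself was not tested and stays open. Expected counts at 1 pair of pixels of the cluster, 69.4 in WT and 32.5 in FS at pixels 30 kb apart, had been seen before this test. They differ in the direction of a higher WT background, though at unlike distances. The FS list did call a loop from one of these anchors to the cluster, 30 kb from the WT one, so a shift of the called pixel could produce part of the difference. Of the 2 IGF2BP1 loops, 1 passed the FS limits in 49 of 100 thinnings, so depth stays open for it. The same comparison gave 0.698 at PBX3, near the 0.727 of its whole chromosome, and 0.588 at the 1 shared loop near SOX4, so lower coverage in the FS map stays a possible explanation at both.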
